A study of Cyanidioschyzon merolae strain 10D with 4 samples.

How the data were processed

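Messenger RNA levels were measured by RNA sequencing in wild-type cells of Cyanidioschyzon merolae strain 10D, a unicellular red alga. The labels describe 4 libraries: 2 from cells kept in darkness and 2 from cells given blue light at 15 µmol per square metre per second for 30 minutes. Per the labels' protocols, RNA was extracted with Trizol and the libraries were made from total RNA with an Illumina TruSeq kit. The sample labels do not say whether the libraries of a condition came from separate cultures, although the series' design text calls them biological duplicates. If they did not, the p-values measure only the spread between these libraries, which may be technical. Groups were taken from the sample titles. The series title also names red light, and its design text names qRT-PCR; neither was analysed here.

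The authors aligned the reads with TopHat2 2.0.5 and compared the conditions with Cuffdiff, per the submitters' processing notes. The version of Cuffdiff, the genome build, the annotation and the normalization method are not given in the sources used here. The authors' deposited table holds 1 value per condition in FPKM, fragments per kilobase of gene scaled to the sequencing depth, per the file headers. It also holds the log2 fold change of blue light over darkness, deposited by the authors, and a test statistic, a score from the authors' Cuffdiff run that was not used here. Per the file headers, each gene further has a p-value and a q-value of the authors' test. The deposited log2 fold change equalled the log2 ratio of the FPKM values to within 1.24e-05. In 77 cells it was replaced by a spreadsheet error, and those cells were treated as missing. Rows without a valid test were left out of all tests, 558 with the status NOTEST and 39 with the status LOWDATA.

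A gene was counted as changed when the authors' q-value was under 0.05 and the test status was valid. The header of the deposited table names a limit of 1.5-fold in addition, but the table's own mark of significance followed q under 0.05 in 100% of tested rows. The direction was read from the FPKM values. Coordinates are printed as deposited. Of the 5100 gene IDs, 4750 matched a locus tag in a reference gene table of assembly ASM9120v1, which gave 0 symbols other than the locus tags. No product names were therefore at hand, and 28 of the 30 gene lists fixed before the data were examined, all defined by product name, could not be filled. The lists of plastid-encoded and mitochondrion-encoded genes were filled from the deposited chromosome names. By the rule fixed for this case, the text names the 2 genes with the largest rise and the 2 with the largest fall among changed genes that shared their locus with no other gene and had at least 1 FPKM in both conditions. Other features are given by position, and those were chosen after their values were seen.

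List members were compared with the other tested genes at unshared loci by two-sided Fisher's exact tests, separately for rises and falls, with Benjamini-Hochberg adjustment. A list with fewer than 3 tested members was not tested. The tests treat genes as independent. The median log2 fold change of a list was placed among 10000 random lists of the same size matched on deciles of mean log2 FPKM. Tests of medians, positions and orders were permutation tests with fixed seeds.

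The deposited values were also searched for the worth of a single fragment. For genes at unshared loci spanning at least 650 bp, values in each condition fell on sums of whole fragments from 2 libraries, each with its own step, where the step depended on the gene's span less a fitted length. Among values for which fewer than 0.05 solutions were due by chance, 99.8% of 1261 darkness values and 99.9% of 1700 blue light values had a whole-fragment solution within the rounding of 6 digits. With decoy steps the share was between 1.82% and 2.22%. Requiring the solutions to give the deposited log2 fold change as well left exactly 1 solution for 3031 of 3781 genes. The same search on simulated fragments for 3756 genes left 1 solution for 2878 genes, of which 100% were right. The recovered libraries could not be matched to replicate numbers and are called the deeper and the shallower library of their condition. The fitted steps correspond to scaled depths of 845127 and 643989 fragments in darkness and 540167 and 418040 fragments under blue light.

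Per-library FPKM of the 2888 tested genes with recovered fragments were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) with a mean-dependent prior and Benjamini-Hochberg adjustment. This test was added after the data were seen. Fold changes on that scale understate the change of low genes. In a simulation of this comparison with 2888 genes and a dispersion between libraries set to 0.03, 100 genes were changed 2-fold and 100 4-fold. There, limma recovered 45% of the first and 100% of the second, and 5.23% of its 153 calls were false. Far more genes were called in the data, 1579 of 2888, so these simulated rates need not hold for them. Alternatives to the main count were a q-value under 0.01, an absolute log2 fold change of at least 1, a 1.5-fold limit, adjustment over nuclear genes, minimum mean FPKM of 1 and 10, single-gene rows and centring on the median. For plastid-encoded genes, all tested genes and changes in either direction were added after the data were seen. Other pseudocounts of 0.1 and 10 and leaving out each recovered library were tried with limma. Other calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.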

Results

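Transcript levels in Cyanidioschyzon merolae, a unicellular red alga with nuclear, plastid and mitochondrial genomes, were compared between 2 libraries from cells in darkness and 2 libraries from cells exposed to blue light for 30 minutes. The authors' deposited table listed 5100 genes, of which 4796 lay on the 20 nuclear chromosomes, 244 on the plastid genome and 60 on the mitochondrial genome. A valid test was available for 4503 genes. The table gave 1 FPKM value per condition, so that values taken from it carry no spread of their own. Fragments recovered from these values amounted to 335091 and 255324 in the darkness libraries and 225529 and 176302 in the blue light libraries, over the 3031 genes for which the recovery was unique. The tested genes among them had a median of 163 fragments in darkness and 108 under blue light, summed over both libraries of a condition.

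The comparison addressed which genes respond to blue light. By the authors' deposited table, 2396 of 4503 tested genes changed at a q-value under 0.05, or 53.2%. Of these, 1220 genes rose and 1176 fell, which is 27.1% and 26.1% of the tested genes. Among the called genes, rises were larger than falls. The median rise in the authors' deposited table was 1.34 on the log2 scale, or 2.54-fold, with quartiles of 0.91 and 2.08. The median fall in the same authors' deposited table was -0.98, or 1.98-fold, with quartiles of -1.38 and -0.75. The difference of 0.36 between the median sizes passed a two-sided permutation test over genes (p = 1e-05, the smallest that 100000 resamples can give), in which genes are not independent replicates and which covers only called genes, chosen in part by the size of their change. Over all tested genes with a finite fold change, the quartiles in the authors' deposited table were -0.65 and 0.74, with a median of -0.017. Among genes with values above 0 in both conditions, at least 4-fold changes were called for 332 rises and 125 falls in the authors' deposited table, and at least 16-fold changes for 62 rises and 27 falls.

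**Figure D1:**
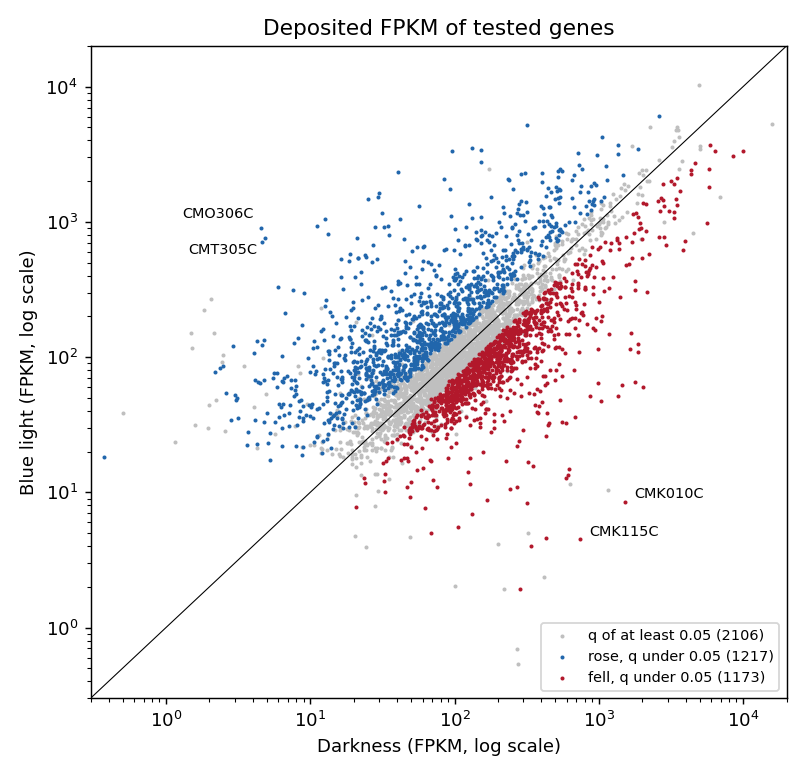
Each point is 1 tested gene with a deposited FPKM above 0 in both conditions, darkness on the x axis and blue light on the y axis, both in FPKM on a log scale, and the line marks equal values. The 1217 rises and 1173 falls with a q-value under 0.05 lie on either side of the line, and the 4 named genes lie far from it.

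The 2 named genes that rose most were CMO306C and CMT305C, and no name or product was at hand for either. CMO306C, on chromosome 15 from 763737 to 764899, rose from 4.54 to 908 FPKM in the authors' deposited table, a log2 fold change of 7.64 with a q-value of 0.017. Its recovered fragments numbered 5 and 2 in the darkness libraries and 453 and 407 in the blue light libraries. CMT305C, on chromosome 20 from 772119 to 773418, rose from 4.85 to 759 FPKM in the authors' deposited table, a log2 fold change of 7.29 with a q-value of 0.0064. Its darkness value corresponded to 4 fragments in each library. The 2 named genes that fell most both lay on chromosome 11. CMK010C, from 24880 to 26285, fell from 1516 to 8.55 FPKM in the authors' deposited table, a log2 fold change of -7.47 with a q-value of 0.00021. CMK115C, from 320822 to 323145, fell from 741 to 4.49 FPKM in the authors' deposited table, a log2 fold change of -7.37 with a q-value of 0.00021. The blue light values corresponded to 10 fragments in all for CMK010C and 9 for CMK115C. The lower value of each named gene thus rested on 7 to 10 fragments.

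Transcripts listed at 0 in 1 condition were rare among tested genes. The authors' deposited table held 7 such genes, with 17.5 to 315 FPKM in the other condition. It called 3 of them as rises and 3 as falls, and 1 plastid gene did not pass. On chromosome 14, the gene from 122299 to 122978 had 315 FPKM in darkness and was listed at 0 under blue light in the authors' deposited table. On chromosome 10, the gene from 808917 to 809965 was listed at 0 in darkness and had 183 FPKM under blue light in the authors' deposited table.

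The balance of rises, falls and other genes differed between deciles of transcript abundance (permutation test of the calls, p = 1e-05, the smallest that 100000 resamples can give). In the lowest decile of tested genes by mean FPKM of both conditions, from 8.73 to 39.1 FPKM, the authors' deposited table called 148 rises and 36 falls. In the sixth decile, from 109 to 137 FPKM, it called 96 rises and 134 falls. In the highest decile, from 436 FPKM upward, the authors' deposited table called 174 rises and 137 falls. The share of changed genes was 40.8% in the lowest and 69.0% in the highest decile. Genes with few fragments are harder to call, so these shares alone do not show a difference in response. The blue light libraries were also shallower than the darkness libraries, so rises and falls of scarce genes need not be equally easy to call. Median log2 fold changes of these 3 deciles in the authors' deposited table were 0.39, -0.19 and 0.19. The most abundant genes took a smaller part of the total under blue light, a comparison with no replicate check: the top 10 genes of each condition held 7.40% of all FPKM in darkness and 5.35% under blue light, and the top 100 held 29.3% and 25.3%. Of the 100 genes with the highest mean FPKM, 23 rose, 41 fell and 36 did not pass the authors' test. The highest value in darkness belonged to a gene on chromosome 11 from 65471 to 65991, with 15914 FPKM in darkness and 5329 under blue light. Its q-value of 0.36 in the authors' deposited table did not pass. All FPKM in darkness came to 1023557, so the difference between the top 10 shares rests in part on this gene.

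**Figure D2:**
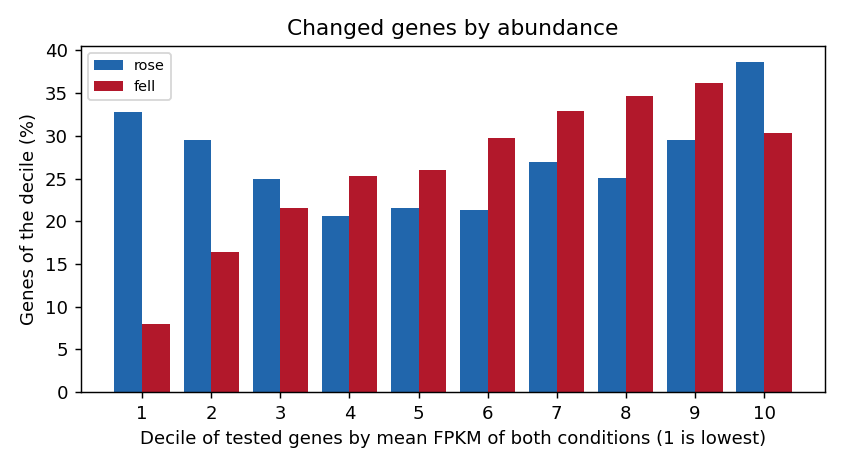
Bars give the percentage of genes that rose and that fell, by the authors' q-value, in each decile of the 4503 tested genes ordered by mean FPKM of both conditions. Rises outnumber falls in the lowest decile, 148 against 36, and falls outnumber rises in the sixth, 134 against 96.

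On the plastid genome, 53 genes were tested, of which 13 rose, 5 fell and 35 did not pass in the authors' deposited table. The highest number of rises in 8 adjacent tested genes was 6, between 83355 and 91751. In that run, log2 fold changes of the rises in the authors' deposited table ran from 1.97 to 3.72, or 3.92-fold to 13.2-fold. The largest, from 86349 to 88593, went from 12.2 to 162 FPKM, and the gene from 83355 to 85164 went from 234 to 2088 FPKM, both in the authors' deposited table. Within the same run, the gene from 85369 to 85642 fell from 4620 to 2727 FPKM in the authors' deposited table, by 0.76 on the log2 scale, and 1 gene with a log2 fold change of 1.25 did not pass. Of the 6 rises, 4 lay at loci of their own, while the other 2 shared a locus, where the authors' counting could divide fragments between genes. A gene at a shared locus outside the run, from 125097 to 125999, went from 174 to 2447 FPKM in the authors' deposited table. Its log2 fold change of 3.82 was above the largest in the run, but its q-value of 0.35 did not pass. The 7 called rises on the plastid genome outside the run had log2 fold changes of 0.98 to 2.49 in the authors' deposited table. The deepest falls there, -1.78 and -1.73 in the authors' deposited table, were of 2 genes within a single locus of 11 genes from 70620 to 80420.

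**Figure D3:**
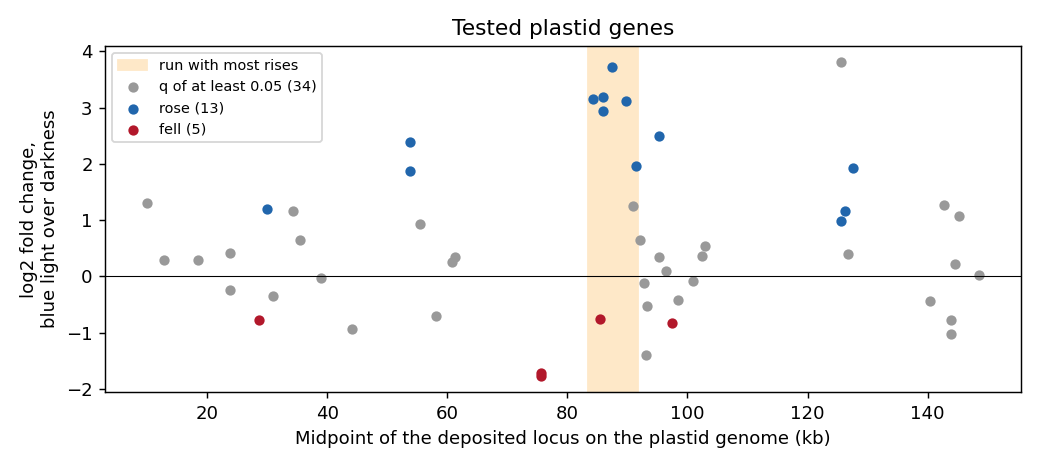
Points are tested plastid genes with a finite deposited log2 fold change of blue light over darkness on the y axis, at the midpoint of their deposited locus in kb on the x axis, and shading marks the run of 8 tested genes with most rises. The shaded run holds 6 of the 13 rises, with log2 fold changes of 1.97 to 3.72.

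Fewer of the plastid-encoded genes were called as changed than of the others when all tested genes were counted. A lower share of calls need not mean fewer changes, since a change can miss the test. No valid test was available for 191 of 244 plastid genes, against 348 of 4796 nuclear genes. By the authors' deposited table, 18 of 53 plastid genes changed, or 34.0%, against 53.4% of the other 4450 genes (two-sided Fisher's exact test, adjusted p = 0.0080 over 3 tests), and 9.43% fell against 26.3% (adjusted p = 0.0080). Rises made up 24.5% against 27.1% and did not pass (adjusted p = 0.76). These comparisons, added after the data were seen, include genes that share a locus and are not independent. With genes at unshared loci alone, as fixed before the data were examined, neither direction passed. Among the 28 tested plastid genes at unshared loci, 6 rose, 3 fell and the others did not pass, both by q-values over all genes and when adjusted over the list alone. The share of rises was 21.4%, against 27.5% of the other 4276 genes, and did not pass a two-sided Fisher's exact test (adjusted p = 0.67, 2 tests). The share of falls was 10.7%, against 26.6%, and did not pass either (Fisher's exact test, adjusted p = 0.17). Changes in either direction made up 32.1% against 54.1% (adjusted p = 0.068 over 3 tests). The median log2 fold change of these plastid genes, 0.38 from the authors' deposited table, lay at percentile 87.8 of random lists matched on abundance. Plastid genes held 2.96% of all FPKM in darkness and 2.85% under blue light.

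Of 60 mitochondrial genes, 2 were tested, too few for a list test. The gene from 2151 to 3297 fell from 93.9 to 29.7 FPKM, a log2 fold change of -1.66 with a q-value of 0.00088 in the authors' deposited table. The other, from 26868 to 28364, had 53.7 FPKM in darkness and 69.4 under blue light, with a q-value of 0.28 in the authors' deposited table. The median log2 fold change of the 2 genes, -0.64, lay at percentile 13.1 of random lists.

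Changed genes were spread over all 20 nuclear chromosomes. The share changed in the authors' deposited table ran from 47.4% of 340 genes on chromosome 18 and 47.4% of 97 on chromosome 1 to 63.0% of 127 on chromosome 6. Rises made up 34.1% of the tested genes of chromosome 10 and 20.3% of those of chromosome 4. Differences between chromosomes did not pass a permutation test of the calls, for all changed genes (adjusted p = 0.37 over 3 tests), for rises (adjusted p = 0.37) or for falls (adjusted p = 0.65).

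Within a condition, the recovered libraries resembled each other more than libraries of the other condition. Across the 3031 genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.968 between the darkness libraries and 0.943 between the blue light libraries, and 0.670 to 0.694 between conditions. The difference between the libraries of a condition had an SD of 0.40 on the log2 scale in darkness and 0.47 under blue light. The limma test on these libraries called 1579 of 2888 genes at an adjusted p under 0.05, 834 higher and 745 lower under blue light. It shared 1436 calls with the authors' test on the same libraries, or 96.6% of the authors' 1486 calls for these genes, with 0 in the opposite direction. The shared direction was nearly fixed, since the recovered fragments had to give the deposited log2 fold change. The shared calls are therefore no independent check. Abundant genes were under-represented here, since the tested genes with recovered fragments had a median mean FPKM of 86.8 and those without 196.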

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

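Some genes without a valid test had higher values under blue light than in darkness, in data that no test addressed. Of the 597 such genes, 35 had a blue light value of at least 10 FPKM that was at least 2 times the darkness value, 27 of them nuclear and 8 on the plastid genome. For comparison, 38 genes met the same limits in the opposite direction, 20 of them nuclear and 18 on the plastid genome. The highest blue light value among the 35 was 716 FPKM, for a gene spanning 114 bp that was listed at 0 in darkness. The highest darkness value among the 38 was 2864 FPKM, for a gene spanning 188 bp that was listed at 0 under blue light. These values have no test, and 221 of the untested genes were listed at 0 in both conditions. The fitted length taken off a gene's span in the recovery was 162 to 173 bp. A span of 114 bp is shorter than that, and one of 188 bp is little longer, so the FPKM values of these short genes are uncertain.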

How the results depend on the processing

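The 1.5-fold limit, every alternative that uses limma and the plastid comparisons over all tested genes were chosen after seeing the data. Requiring an absolute log2 fold change of at least 1 lowered the count of changed genes from 2396 to 1421 and that of falls from 1176 to 567, because the added limit removes smaller changes, while 854 of 1220 rises were left. Under the same limit the odds ratio of rises among plastid-encoded genes turned from 0.72 to 1.15, with neither passing the test (adjusted p = 0.67 and 0.81); the cause was not tested. For plastid-encoded genes, including those at shared loci changed the odds ratio of falls from 0.33 to 0.29 and that of changes in either direction from 0.40 to 0.45, and both then passed (adjusted p = 0.0080), with more genes tested. At a q-value under 0.01 the odds ratio of falls was 0.15 (adjusted p = 0.060), and with a log2 limit of 1 its adjusted p was 0.083. The plastid median of 0.38 lay at percentile 94.9 of random lists not matched on abundance, against 87.8 with matching. The other settings left between 1862 genes, at a q-value under 0.01, and 2396 genes. Among genes with recovered fragments, limma called 1569 with a pseudocount of 0.1 and 1620 with 10, against 1579 with 1. Leaving out each recovered library in turn gave 1285 to 1603 genes, 734 to 815 of them rises and 551 to 788 falls, where the lone library of a condition is assumed to vary like those of the other. Centring and the minimum FPKM of 1 say nothing about stability here: centring shifted values by 0.017, less than the smallest called change of 0.45, and the filter removed 0 changed genes. The named genes were chosen for changes too large for a pseudocount of 1 to turn. No paired analysis was possible because the columns carry no replicate number. The list background without hypothetical products was not run, since no product names were at hand, and leaving out labelled replicates was not possible with 1 deposited value per condition. Depth limits the low values: the lower value of each named gene rests on 7 to 10 fragments.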

Other observations

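The tests of runs of large changes, of large uncalled changes, of the genes of equal span and of the plastid run were chosen after the result was seen; those of neighbouring genes and of chromosome ends were written down before. Large changes also came in short runs along chromosomes. The tests of runs, neighbouring genes and chromosome ends used only tested nuclear genes at unshared loci. Genes called adjacent here can therefore have another gene between them. Runs of at least 3 such adjacent genes, all called and changed at least 8-fold in the same direction, occurred 2 times. Searched over runs of at least 2, 3 or 4 genes and changes of at least 4-fold, 8-fold or 16-fold, 4 of the 9 settings passed alone. Chance placement gave as extreme a result with a permutation p of 0.0025 over the whole search. The shuffles speak only against placement at random. They cannot tell regulation shared by close genes from reads spilling over between them. On chromosome 3, from 380215 to 387612, 3 genes went from between 4.49 and 10.5 FPKM in darkness to between 64.3 and 135 FPKM under blue light in the authors' deposited table. On chromosome 13, from 388142 to 398047, 3 genes went from between 14.5 and 101 FPKM to between 142 and 882 FPKM in the authors' deposited table. At the limits of 3 genes and 8-fold, there was 1 more run without regard to the authors' call, on chromosome 10 from 807870 to 817475, where the authors' deposited table gave 1.84, 0 and 2.04 FPKM in darkness and 224, 183 and 271 FPKM under blue light. The authors' test called only the gene listed at 0 in darkness, while limma on the recovered libraries called the other 2, with adjusted p of 2.9e-07 and 2.6e-07. That outcome was nearly fixed, since these genes were chosen for differing at least 8-fold.

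Leaving out the 7 tested genes listed at 0 in 1 condition, 211 genes differed at least 8-fold in the authors' deposited table, and 32 of them, 22 higher and 10 lower under blue light, did not pass the authors' test. The limma test on the recovered libraries called 12 of the 12 uncalled genes with all libraries recovered, an outcome nearly fixed by choosing genes that differ at least 8-fold. In the lower condition, 16 uncalled genes had 1 to 4 fragments, with a median of 2. The 148 called genes had 5 to 573 fragments there, with a median of 29.5, so the ranges did not overlap. The medians differed in a one-sided permutation test (p = 1e-05, the smallest that 100000 resamples can give). Whether few fragments kept the uncalled genes from being called stays open, since 6 of the 7 genes listed at 0, which this test leaves out, were called. Disagreement between the libraries of a condition stays open: in the higher condition, the median absolute log2 difference between libraries was 0.18 in 12 uncalled and 0.19 in 76 called genes, a difference of -0.015 with a 95% bootstrap interval of -0.086 to 0.066, and the lower condition holds too few fragments to tell; no biological explanation was tested.

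Adjacent nuclear genes changed slightly alike, with genes at shared loci left out. Across 4243 pairs, Pearson's r of the log2 fold changes was 0.085 and Spearman's rho 0.095 (permutation p of r = 0.0001, the smallest that 10000 shuffles can give). For genes 2 places apart r was 0.009, and for genes 3 places apart it was 0.028. The resemblance lay in close pairs: r was 0.172 among pairs with a gap up to the median of 1692 bp and 0.016 among pairs with larger gaps, under the shuffled limit of 0.043. This is consistent with reads spilling over between close genes, but regulation shared by close genes would give the same pattern and was not tested. Whether abundant genes lend reads to scarce neighbours stays open: r differed by -0.054 between pairs with the largest and the smallest abundance difference, within the shuffled limits of -0.080 and 0.081.

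Of the 30 deepest falls among tested genes at unshared loci, 4 genes on chromosomes 3, 8, 13 and 17 spanned 1887 or 1888 bp. They had 220 to 432 FPKM in darkness and 0.54 to 4.61 FPKM under blue light in the authors' deposited table, log2 fold changes of -6.55 and lower, and 1 of the 4 was called. The other 4 tested genes of that span had log2 fold changes between -1.38 and 0.79. Fractional assignment of reads between near-identical copies could leave fractions of a fragment, but all 4 blue light values were whole, at 8, 1, 3 and 1 fragments. This argues against fractional assignment in the blue light values only. The darkness values were not part of this test, and it does not address why the values fell. Placement of whole reads among similar copies stays open, since sequences were not used here.

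For the run of rises on the plastid genome, chance placement was not excluded. With runs of 8 genes alone, 13 rises placed at random gave 6 in a run with a permutation p of 0.042, but that length was taken from the data. Searched over the 8 run lengths from 5 to 12 genes, the p was 0.054. Genes near chromosome ends did not change more than others. The 400 tested nuclear genes at unshared loci nearest the ends had a median absolute log2 fold change of 0.70, at percentile 62.6 of random sets.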
